A study of Macaca mulatta with 10 samples.

How the data were processed

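Gene expression was measured in micro-punches of the dorsal thalamus of untreated adult rhesus monkeys (Macaca mulatta). Total RNA was labelled with biotin and hybridised to an Affymetrix short-oligonucleotide array designed for human transcripts. The 10 arrays came from 5 nuclei, named on the labels as Anterior Thalamus, Centre Median, Medial Thalamus, Pulvinar and Ventral Thalamus, with 2 arrays of each. The labels number the arrays of a nucleus as replicates 1 and 2 and do not say whether they came from separate animals.

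The deposited values are normalized intensity values that the authors computed with RMA, per the submitters' processing notes, which give no version. RMA subtracts background, normalises probe intensities across the arrays processed together and summarises the probes of each probe set. The values were deposited on the linear scale, so log2(value + 1) was used throughout, with a pseudocount of 1. The lowest intensity was 12.0 to 12.3 on the replicate 1 arrays and 9.49 to 9.55 on the replicate 2 arrays, so the lower end of the scale differed between the sets of arrays. Whether the 2 sets were normalised together or separately is not stated, and the difference between replicate numbers was not separated from such a step. The files hold no detection calls, and a probe designed for a human transcript may bind its rhesus counterpart more weakly, so a low intensity was not read as absence of the transcript. For arrays no count depth applies, and the number of arrays limits the precision.

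The table held 22283 probe sets, of which 68 were hybridisation and labelling controls. The annotation listed 20114 of the probe sets, and 1043 of these were assigned to several genes. Probe sets with exactly 1 gene symbol that were not controls numbered 19065, and a further 2107 were left out because the annotation did not list them. For the 4310 genes with more than 1 probe set, the probe set with the highest mean over all 10 arrays was taken, which left 11963 genes. No filter on low values was applied. No genome build is given with these values, so genes are identified by symbol and no coordinates are stated.

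The comparisons, the gene lists, the rule for named genes and the other settings to be tried were chosen before the data were examined. A linear model with 1 coefficient per nucleus was fitted to each gene with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend of the variance with the mean. Each nucleus was compared with the mean of the other 4 nuclei, all nuclei were compared with a moderated F statistic, and each of the 10 pairs of nuclei was compared directly. The comparisons with the rest are not independent, since a shift in 1 nucleus moves the differences of the other 4 nuclei the opposite way. Benjamini-Hochberg adjustment covered all genes within a comparison, and a gene was called at an adjusted p under 0.05. The fit without a block had 5 residual degrees of freedom and 2.91 prior degrees of freedom. A nucleus-specific gene was one called against the rest whose 2 arrays both lay above, or both below, the 8 other arrays and whose mean differed from each of the other 4 means by at least 1.5-fold. In the fit with the replicate number as a block, described below, the arrays were compared after the fitted shift between replicate numbers was subtracted. For values as they are, chance places 2 given arrays of 10 highest in 2.22% of orderings.

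Whether the replicate numbers pair the arrays across nuclei was checked from the values, by correlating the difference between replicate 2 and replicate 1 across genes between nuclei. All 10 correlations exceeded 0.1, at 0.758 to 0.831, and the numbers were therefore treated as paired. A second fit, with the replicate number as a block, had 4 residual and 8.66 prior degrees of freedom, and its result is printed beside that of the fit without a block. The median residual standard deviation on the log2 scale was 0.220 without the block and 0.126 with it. The p-values of both fits measure only the spread between these arrays, since the number of animals is not stated on the labels.

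Shifts of gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, for 34 lists fixed beforehand and 5 comparisons, giving 170 tests that were adjusted together. camera asks whether the members of a list rank higher or lower than all other genes. Calls of single members were counted over all genes and adjusted over the list alone. The lists were chosen from general knowledge of thalamic cell types and pathways and not from these arrays. Similarity of replicates was tested with a one-sided exact permutation test of the mean Euclidean distance between arrays of a nucleus over the 1000 genes with the highest variance, across all 945 ways to split 10 arrays into pairs. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

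Named genes were taken by rule. For each nucleus these were, among called genes whose 2 arrays lay beyond all 8 other arrays, the 12 largest increases and the 8 largest decreases, and further called members of the fixed lists, at most 6 per list. Where fewer than 10 genes were called, the 10 with the smallest unadjusted p were named as not called. The 15 genes with the smallest p of the F test and the 2 largest called differences of each pair of nuclei were also named. CALB1, CALB2, PVALB, SLC17A6, GAD1, GFAP, MBP and TCF7L2 were named whatever their result. The same rule was applied to the fit with the block, where the arrays were compared after the fitted shift between replicate numbers was subtracted.

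The fits were tested on simulated data, with 200 of the 11963 genes changed at the spread of these arrays in each of the 5 comparisons. Without the block, 5.97% to 11.9% of genes changed 1.5-fold, 50.7% to 61.2% of genes changed 2-fold and 87.9% to 95.5% of genes changed 4-fold were called, and 0 unchanged genes were called. With the block, 88.1% to 98.5% of genes changed 1.5-fold and 100% of genes changed 2-fold or 4-fold were called, together with 10 to 25 unchanged genes. Unchanged genes made up 4.78% to 11.5% of the blocked calls, above the nominal 5% in 4 of the 5 comparisons, with 1 simulated data set per comparison, so blocked calls near the threshold are less certain than their adjusted p states. The simulated errors were independent between genes. Errors shared by many genes on an array were not simulated, so these shares may not hold for the real arrays.

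The other settings chosen beforehand were quantile normalisation, median centring, filters on low values, other rules for several probe sets of a gene, other variance priors, array weights, leaving out each array in turn, other thresholds, a pseudocount of 16, other list tests and other distances. Added after the data were seen were the combination of the block with each of these, the block with the 3' minus 5' signal of the actin or GAPDH controls as a covariate, the block with a split of the replicate 1 arrays by XIST and RPS4Y1, list tests after quantile normalisation, and distances restricted to pairings across replicate numbers. No array was left out of the comparisons.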

Results

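Transcript levels of 11963 genes were compared among 5 nuclei of the dorsal thalamus of the rhesus monkey, with 2 arrays of each nucleus and 10 arrays in all. The thalamus relays sensory, motor and associative signals to the cortex. Its ventral nuclei serve sensory and motor relay, the pulvinar serves visual association, the anterior nuclei belong to limbic circuits, and the centre median is an intralaminar nucleus that projects to the striatum. The study asked which genes are unique to each nucleus. The values are log2 intensities, and median intensities of the arrays lay between 94.2 and 100.6.

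The largest difference among the arrays was the replicate number and not the nucleus. The first principal component held 68.6% of the variance and placed the 5 replicate 1 arrays between 14.8 and 31.97 and the 5 replicate 2 arrays between -29.2 and -17.7. The second component held 6.88% and placed the Ventral Thalamus arrays at -10.7 and -14.0 and the Medial Thalamus arrays at 5.04 and 11.9. Across genes, arrays of different nuclei with the same replicate number correlated at 0.979 to 0.992, and arrays of the same nucleus at 0.940 to 0.961. With limma and the replicate block, 3044 genes were higher and 3724 were lower in replicate 2. The labels do not say whether the 2 sets came from separate animals or were normalised separately, so this difference was assigned to neither. Every difference among nuclei is therefore given without and with the replicate number as a block.

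**Figure D1:**
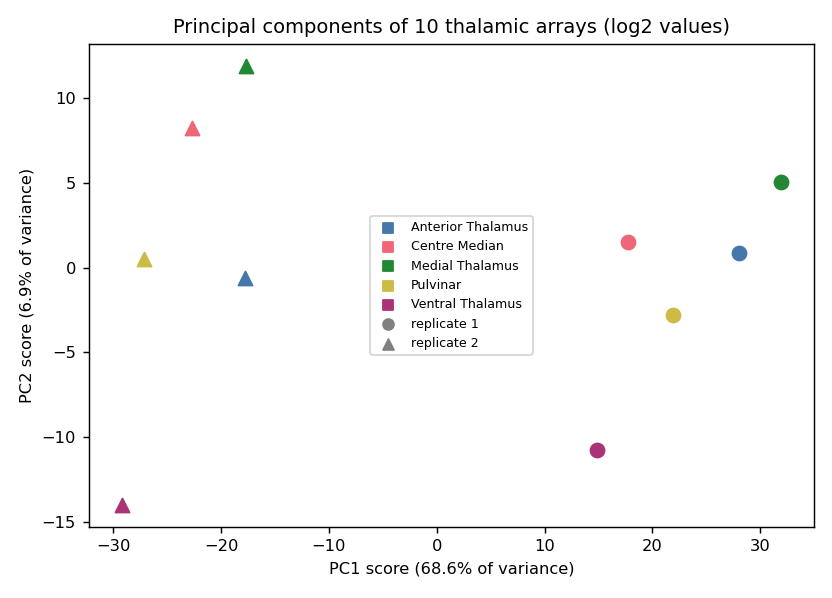
Each point is 1 of the 10 arrays, plotted by its scores on the first (68.6% of variance) and second (6.88%) principal components, with colour for the nucleus and shape for the replicate number. Replicate 1 arrays lie at 14.8 or more on the first axis and replicate 2 arrays at -17.7 or less.

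The actin control, probed near both ends of its transcript, also differed among the arrays. Its log2 3' minus 5' signal, which rises as RNA is degraded or incompletely copied, was 0.37 for Anterior Thalamus, 0.46 for Centre Median, -0.09 for Medial Thalamus, 0.34 for Pulvinar and 1.22 for Ventral Thalamus in replicate 1. In replicate 2 the values were 1.36, 1.15, 1.34, 1.27 and 1.64 in the same order. The Ventral Thalamus array had the highest value in each replicate set.

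**Figure D2:**
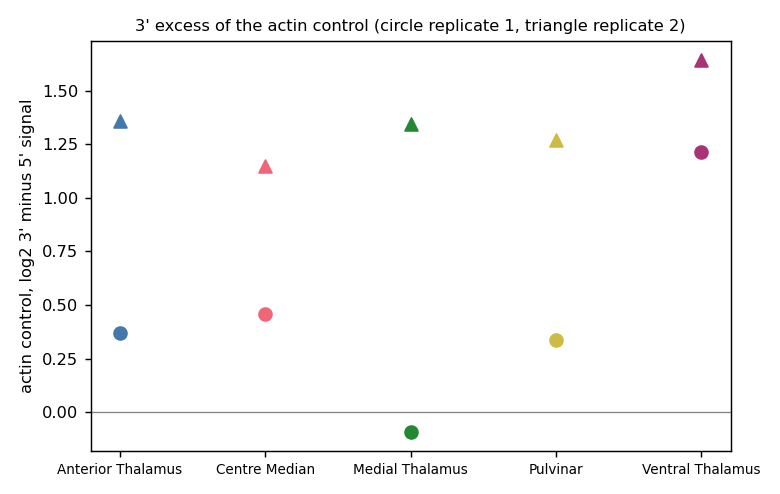
The log2 3' minus 5' signal of the actin control is shown for each array, with circles for replicate 1 and triangles for replicate 2. Ventral Thalamus stood at 1.22 in replicate 1, where the other nuclei lay between -0.09 and 0.46, and at 1.64 in replicate 2, where they lay between 1.15 and 1.36.

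The 8 marker genes fixed beforehand gave the general character of the punches. TCF7L2, a transcription factor of the developing and adult thalamus, had means between 12.23 and 12.70 in the 5 nuclei, and SLC17A6, the vesicular glutamate transporter of thalamic relay neurons, had means between 10.44 and 11.20. MBP, a myelin protein, ranged from 12.56 in Medial Thalamus to 13.36 in Ventral Thalamus. CALB2, which encodes the calcium-binding protein calretinin, differed among nuclei with the block (adjusted p = 0.00717 by limma F test), with its highest mean of 10.05 in Medial Thalamus and its lowest of 8.14 in Ventral Thalamus. GFAP, the intermediate filament of astrocytes, differed as well (adjusted p = 0.0285), from 11.82 in Medial Thalamus to 10.03 in Ventral Thalamus. PVALB, the calcium-binding protein parvalbumin, had means of 10.93 in Ventral Thalamus, 10.85 in Centre Median, 9.83 in Pulvinar, 8.78 in Anterior Thalamus and 8.60 in Medial Thalamus and did not pass (adjusted p = 0.0932). GAD1, the GABA-synthesising enzyme (adjusted p = 0.0738), SLC17A6 (0.219), MBP (0.355), TCF7L2 (0.712) and CALB1, which encodes calbindin (0.893), did not pass either. Without the block none of these 8 genes passed.

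The F test across all 5 nuclei asked which genes differed in any way. MC4R, the melanocortin receptor targeted by appetite-regulating peptides, had the smallest p in both fits. Its mean was 8.21 in Centre Median and 6.33 to 6.53 elsewhere. With the block 47 genes passed (1158 at an unadjusted p under 0.05), and without it limma called 0 genes (86 at an unadjusted p under 0.05), with a smallest adjusted p of 0.0692 for MC4R. The 15 genes with the smallest p in the blocked fit, with adjusted p from 4.49e-05 to 0.0135, were MC4R, TPBG, HS3ST1, OPN3, DIRAS3, STK39, ATP2B1, CBLN1, LMO1, NPTX2, EPHA4, CALB2, SERPINI1, CRYM and DPYSL3. Centre Median had the highest mean for MC4R, TPBG, DIRAS3, CBLN1, LMO1, EPHA4, SERPINI1 and CRYM. Ventral Thalamus had the highest mean for HS3ST1, OPN3 and STK39, and Medial Thalamus had the highest for CALB2 and DPYSL3. The 15 without the block included also PCP4, MAG, PENK, LOC728392, RYR3 and CHST15. The blocked count of 47 was 29 without Anterior Thalamus replicate 1, 13 without Centre Median replicate 1, 85 without Medial Thalamus replicate 1, 95 without Medial Thalamus replicate 2 and 22 without Ventral Thalamus replicate 2.

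Centre Median had the clearest single-gene differences from the other nuclei. MC4R stood at 8.21 ± 0.05 (SD, n = 2) against a mean of 6.44 in the other 4 nuclei, a 3.43-fold difference. TPBG, a membrane glycoprotein that modulates Wnt signalling, was 2.93-fold higher at 7.66 ± 0.15 (SD, n = 2) against 6.10. DIRAS3, a small GTPase related to Ras, was 2.67-fold higher at 6.86 ± 0.25 (SD, n = 2) against 5.44. These 3 genes passed without the block, with adjusted p of 0.0041 for MC4R, 0.0178 for TPBG and 0.0416 for DIRAS3, and with it at 1.48e-06, 3.49e-05 and 0.000152. limma called 3 genes without the block (119 at an unadjusted p under 0.05) and 21 genes with it, 16 higher and 5 lower (708 at an unadjusted p under 0.05). The unblocked count was 0 without Centre Median replicate 1 and 0 without Centre Median replicate 2. It was 1 without Anterior Thalamus replicate 1 or 2, without Pulvinar replicate 1 or 2 and without Ventral Thalamus replicate 2.

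With the block, CBLN1, a secreted organiser of synapses, was 3.52-fold higher in Centre Median (log2 difference 1.82, SE 0.204, adjusted p = 0.00144). SERPINI1, the neuronal protease inhibitor neuroserpin, differed by 1.58 (SE 0.176, adjusted p = 0.00144), and CRYM, a thyroid hormone-binding protein, by 1.55 (SE 0.181, adjusted p = 0.0019). The other named increases were CACNA2D3, an auxiliary calcium channel subunit, by 1.48, LMO1, a LIM-domain transcriptional regulator, by 1.36, TMEM158 by 1.29, ETV1, an ETS-family transcription factor, by 1.24, LRRC17 by 0.80, ADGRL2, an adhesion receptor of synapses, by 0.79, and EPHA4, an ephrin receptor of axon guidance, by 0.68. The 5 decreases included PCP4, a calmodulin-binding protein, which fell by 1.09 (SE 0.145, adjusted p = 0.00586), and NPTX2, a synaptic pentraxin, which fell by 1.08 (SE 0.119, adjusted p = 0.00144). CITED2, a transcriptional co-regulator, fell by 0.80 and CHST15, a sulfotransferase, fell by 0.71. Without the block the 10 smallest p further included LMO1, SERPINI1, CRYM, PCP4, MINAR1, CACNA2D3 and TTN, with adjusted p of 0.0741 for LMO1 and 0.25 for SERPINI1, and none of these passed. The blocked count of 21 was 4 without Centre Median replicate 1, 32 without Medial Thalamus replicate 1 and 42 without Medial Thalamus replicate 2, and with the replicate 1 arrays split by XIST and RPS4Y1 it was 12, of which 10 were among the 21.

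**Figure D3:**
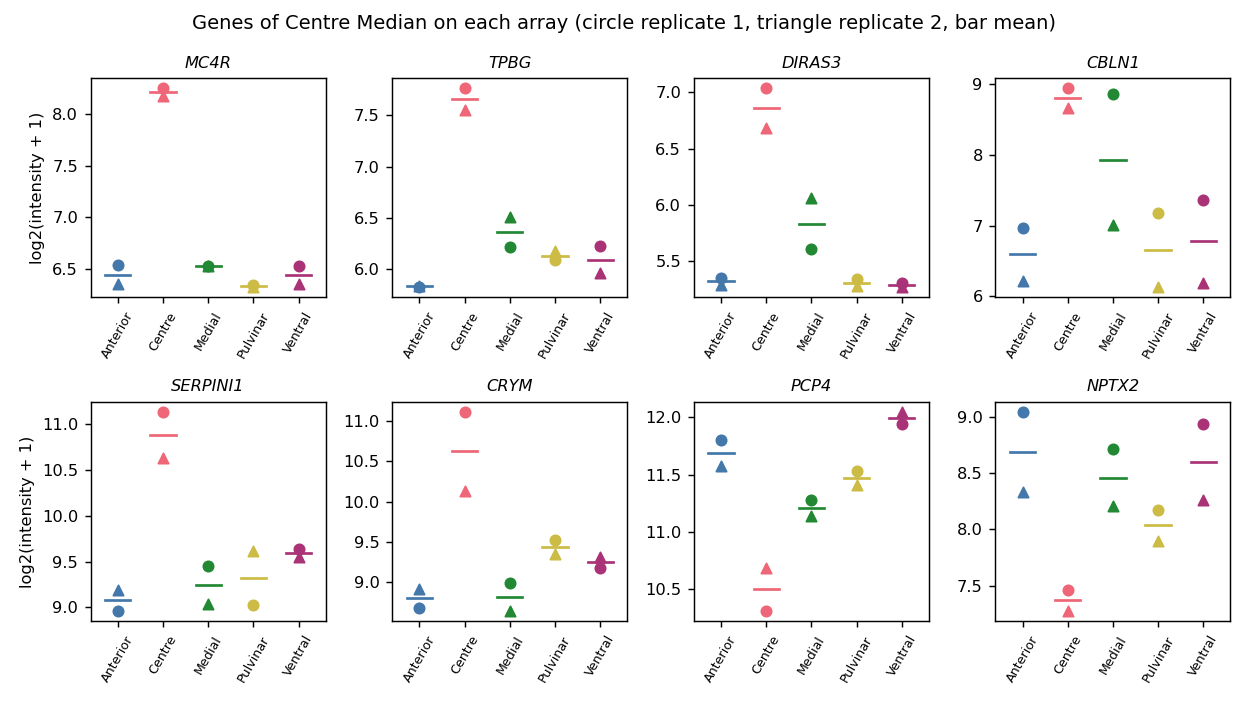
Log2 intensity of 8 genes named for Centre Median is shown on each array, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each nucleus. MC4R has a mean of 8.21 in Centre Median and 6.33 to 6.53 in the other nuclei, and PCP4 and NPTX2 lie lowest in Centre Median.

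Among the fixed lists, genes of oligodendrocytes and myelin were shifted upward in Centre Median, with 18 of 23 measured members above 0 and a median of 0.08 (camera adjusted p = 0.00474 without the block and 0.00171 with it). Medial and Ventral Thalamus, with larger myelin shifts given below, are part of the mean compared with, so this shift is not independent of theirs. Cadherins and adhesion genes were shifted upward, with 19 of 31 above 0 and a median of 0.11 (0.00429 and 0.015). Synaptic vesicle release genes were shifted downward, with 7 of 30 above 0 and a median of -0.11 (0.0347 and 0.0276). Cytosolic ribosomal proteins were shifted upward with the block alone, with 40 of 43 above 0 and a median of 0.10 (0.0835 and 0.00358), and their median was 0.20 in replicate 1 and -0.0041 in replicate 2. Neuropeptides and their receptors passed without the block alone, with a median of 0.02 (0.0475 and 0.0969). In that list MC4R was called over all genes in both fits and CBLN1 with the block, and adjusted over the list alone 4 were higher and 2 lower with the block. In the other 4 lists 0 members were called over all genes in limma. Adjusted over the list alone, with the block, 2 myelin genes and 2 adhesion genes were higher, 1 synaptic vesicle gene was lower and 0 ribosomal genes passed. The midline and intralaminar profile passed in Centre Median in neither fit, although its member CBLN1 was called with the block. No list in any nucleus passed with an estimated correlation: in Centre Median the adjusted p = 0.74 and 0.624 with an estimated correlation for myelin, 0.729 and 0.708 for adhesion, 0.787 and 0.767 for synaptic vesicle release, 0.984 and 0.849 for ribosomal proteins and 0.902 and 0.708 for neuropeptides. The myelin call was lost without the block when Centre Median replicate 2 or Pulvinar replicate 1 was left out (adjusted p of up to 0.375), and with the block when Centre Median replicate 1 was left out (0.147). The adhesion call was lost in both fits without Centre Median replicate 2 or Medial Thalamus replicate 2, and with the block also without Pulvinar replicate 1 (adjusted p of up to 0.279 and 0.416). The synaptic vesicle call was lost in both fits without Anterior Thalamus replicate 2, Centre Median replicate 1 or Medial Thalamus replicate 1, and without the block also without Centre Median replicate 2 (up to 0.359 and 0.358). The blocked ribosomal call was lost without Centre Median replicate 1, Pulvinar replicate 1 or Ventral Thalamus replicate 2 (up to 0.929), and the unblocked ribosomal median was -0.15 without Centre Median replicate 2 and -0.03 without Pulvinar replicate 1. The unblocked neuropeptide call was lost without Anterior Thalamus replicate 2, Centre Median replicate 1, Medial Thalamus replicate 2, Pulvinar replicate 2 or Ventral Thalamus replicate 2 (up to 0.733).

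Ventral Thalamus differed from the other nuclei in single neurofilament and myelin genes, which were called with the block alone. NEFH, the heavy neurofilament subunit of large axons, was 3.36-fold higher at 11.54 against 9.79 (log2 difference 1.75, SE 0.234, adjusted p = 0.0082). NEFM, the medium subunit, was 3.20-fold higher at 11.47 against 9.79 (difference 1.68, SE 0.208, adjusted p = 0.0049), and NEFL, the light subunit, differed by 1.06 (SE 0.183, adjusted p = 0.0241). CALB2 lay 2.43-fold lower at 8.14 against 9.43 (difference -1.28, SE 0.159, adjusted p = 0.0049). limma called 63 genes with the block, 49 higher and 14 lower (1424 at an unadjusted p under 0.05), and 0 without it (188 at an unadjusted p under 0.05). The 10 smallest p without the block were those of B3GALNT1, CALB2, DPYSL3, MAG, NEFH, NEFM, OPN3, PENK, RYR3 and TF, each at an adjusted p of 1.00. The actin 3' minus 5' signal was higher in the Ventral Thalamus array than in the other nuclei in both replicate sets, at 1.22 and 1.64. With that signal as a covariate beside the block, 63 of these 63 genes kept their sign and 0 of the 63 were called. The median ratio of the difference with the covariate to that without it was 0.968, with 9 genes more than 1.5 times smaller and 3 more than 1.5 times larger. ZEB2 went from 1.01 to 0.17, NACC2 from 0.95 to 0.47 and CDS1 from 0.97 to 0.61, whereas CALB2 stood at -1.06 and NEFM at 1.62. NEFH then differed by 2.12, and its call ended as its SE rose from 0.234 to 0.420 (adjusted p = 0.105).

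Other genes called higher in Ventral Thalamus with the block were HS3ST1, a heparan sulfate sulfotransferase, by 1.40 (adjusted p = 0.0015), VAMP1, a synaptic vesicle protein, by 1.31 (0.021), OPN3, a non-visual opsin, by 1.06 (0.00223), STK39, a kinase of ion cotransporters, by 1.04 (0.00147), and ZEB2, a transcriptional repressor, by 1.01 (0.0434). CDS1, a lipid synthesis enzyme, WSB2 and NACC2 differed by 0.97, 0.97 and 0.95. SCN1A, a voltage-gated sodium channel, differed by 0.94 (0.049), PPARGC1A, a coactivator of mitochondrial biogenesis, by 0.93, SHOX2, a homeobox transcription factor, by 0.76, ANK3, an anchor of the axon initial segment, by 0.69, and ESRRG, a nuclear receptor, by 0.58. Among the genes called lower, PLXNC1, a semaphorin receptor, differed by -1.43 (SE 0.240, adjusted p = 0.021), GFAP by -1.11 (SE 0.208, adjusted p = 0.0378) and SCN2A, another sodium channel, by -0.91 (SE 0.134, adjusted p = 0.0137). CA10, B3GALNT1, PENK, the enkephalin precursor, EPHA4, CDH8, a cadherin, and NCALD, a neuronal calcium sensor, fell by 0.86, 0.79, 0.75, 0.66, 0.65 and 0.61. Of 40 comparisons with other probe sets of the genes named for the blocked fit, 32 had the same sign and 8 the opposite sign, the latter for probe sets of MAG, TF, CDS1, WWP1, ANK3, CDH8, HS3ST1 and SHOX2. A shared sign does not mean a similar size. Other probe sets in Ventral Thalamus differed by 0.02 and -0.16 for HS3ST1, 0.45 and 0.12 for VAMP1 and -0.22 for GFAP. Those of PLXNC1 differed by -0.22 and -0.57, those of NEFL by 0.53 and 0.76 and that of NEFH by 1.28. The blocked count of 63 was 0 without Ventral Thalamus replicate 2 and 29 without Ventral Thalamus replicate 1. It was 28 without Anterior Thalamus replicate 1, 37 without Anterior Thalamus replicate 2, 27 without Centre Median replicate 1, 17 without Centre Median replicate 2, 101 without Medial Thalamus replicate 1 and 106 without Medial Thalamus replicate 2. After quantile normalisation with the block it was 28, of which 18 were higher and 27 were among the 63, and with the split by XIST and RPS4Y1 it was 95, of which 57 were among the 63.

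**Figure D4:**
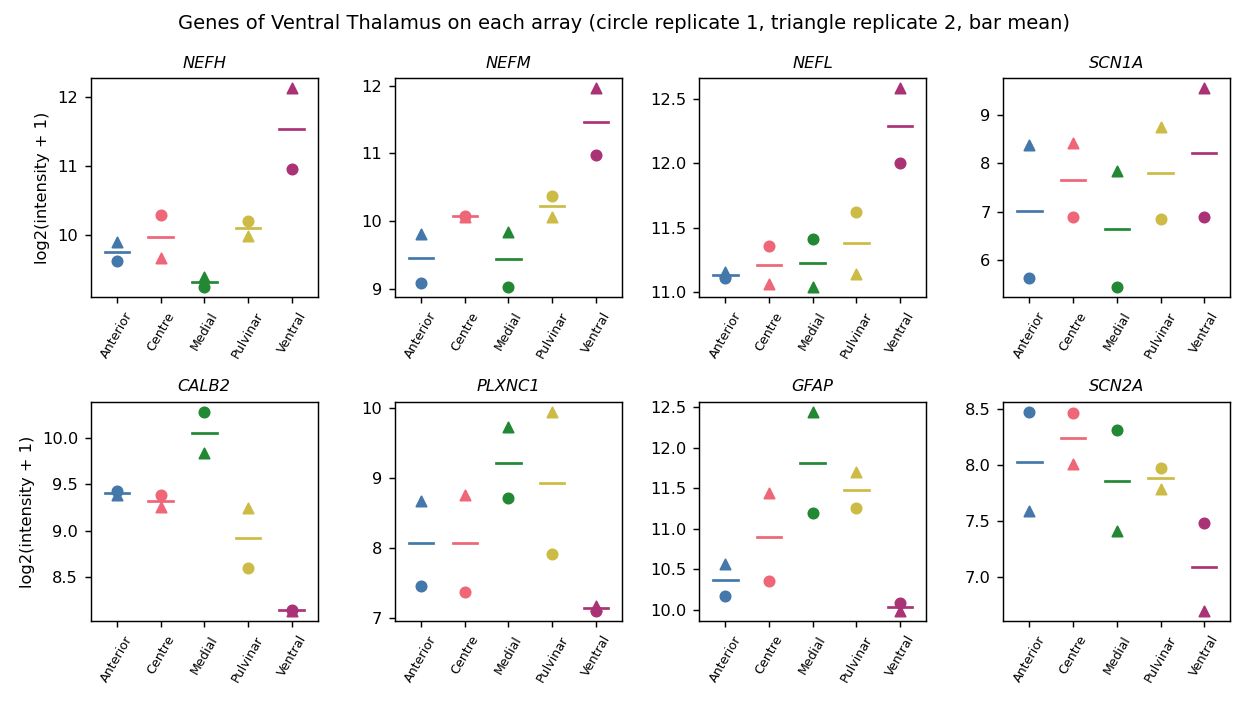
Log2 intensity of 8 genes named for Ventral Thalamus is shown on each array, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each nucleus. NEFH and NEFM have means of 11.54 and 11.47 in Ventral Thalamus, and CALB2 has its lowest mean there, at 8.14.

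Among the fixed lists, mitochondrial oxidative phosphorylation genes, which encode respiratory chain subunits, lay higher in Ventral Thalamus for all 55 measured members, with a median of 0.33 (camera adjusted p = 1.27e-18 without the block and 3.48e-23 with it). Over all genes 0 members were called by limma, and 30 were called with the block adjusted over the list alone. Oligodendrocyte and myelin genes lay higher for 20 of 23, with a median of 0.41 (8.84e-14 and 1.56e-11). The myelin genes CNP, MAG and TF, the last encoding transferrin, were the 3 called over all genes with the block, by 0.87, 0.86 and 0.79, and 14 were called adjusted over the list alone. The first-order relay profile, genes of fast-firing primary relay neurons, lay higher for 11 of 13, with a median of 0.58 (3.32e-09 and 4.38e-08). With the block 5 of its members were called higher, including NEFH, NEFM and VAMP1, and adjusted over the list alone 9 were higher and 1 was lower. Neurofilaments and axonal cytoskeleton genes lay higher for 15 of 21, with a median of 0.31 (7.56e-08 and 2.01e-06). With the block 4 were called over all genes, and adjusted over the list alone 7 were higher and 1 lower. The relay and neurofilament lists share NEFH, NEFM and NEFL, so their results are not separate, here or in the other nuclei. Without the block, adjusted over the list alone, 2 myelin, 3 relay and 3 neurofilament genes were higher and 0 oxidative phosphorylation genes passed. With an estimated correlation the adjusted p = 0.787 and 0.624 for oxidative phosphorylation, 0.315 and 0.229 for myelin, 0.479 and 0.708 for the relay profile and 0.479 and 0.708 for neurofilaments. Beside each of these lists the actin 3' minus 5' signal stood at 1.22 and 1.64 in Ventral Thalamus. Without Ventral Thalamus replicate 2 the unblocked median of oxidative phosphorylation was 0.10 (camera adjusted p = 0.251), and the blocked median was 0.26 (2.8e-12). The myelin, relay and neurofilament lists passed in both fits when any 1 of the 10 arrays was left out, with adjusted p of at most 0.00918, and the blocked oxidative phosphorylation list did so as well.

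Lists shifted downward in Ventral Thalamus included neuropeptides and their receptors, with 7 of 42 members above 0 and a median of -0.11 (camera adjusted p = 9.65e-05 without the block and 0.000295 with it). PENK was the 1 member called over all genes with the block, and 2 were lower adjusted over the list alone. Ephrins, semaphorins and axon guidance genes had 7 of 38 above 0 and a median of -0.08 (0.00132 and 0.000635), with 2 members, PLXNC1 and EPHA4, called over all genes and 5 adjusted over the list alone. The midline and intralaminar profile had 3 of 16 above 0 and a median of -0.09 (0.00226 and 0.00255), with CALB2 called over all genes and 3 members adjusted over the list alone. Without the block, adjusted over the list alone, 1 neuropeptide gene and 1 midline gene were lower and 0 axon guidance genes passed. With an estimated correlation the adjusted p = 0.787 and 0.624 for neuropeptides, 0.541 and 0.471 for axon guidance and 0.787 and 0.624 for the midline profile. Lists of choroid plexus and ependyma (median -0.09, adjusted p = 0.0368 and 0.0969) and of striatum (median -0.08, 0.026 and 0.0969) passed without the block alone, with adjusted p = 0.787 and 0.729 with an estimated correlation. In the choroid plexus list 0 members were called in limma, also adjusted over the list alone, and in the striatum list 1 member, PENK, was lower. Cytosolic ribosomal proteins passed with the block alone, with 35 of 43 above 0 and a median of 0.12 (0.156 and 0.0292; adjusted p = 0.86 with an estimated correlation and the block). Of these 0 members were called, also adjusted over the list alone, and the blocked median turned to -0.02 after quantile normalisation, to -0.09 with the actin signal as a covariate (camera adjusted p = 0.354) and to -0.03 without Ventral Thalamus replicate 1. The actin 3' minus 5' signal of 1.22 and 1.64 stood beside these lists too. Without Ventral Thalamus replicate 2 the unblocked neuropeptide, axon guidance and midline calls were lost (adjusted p = 0.836, 0.174 and 0.879), and with the block those of neuropeptides (0.0835) and of the midline profile (0.117). The unblocked medians without that array were 0.03 for neuropeptides and their receptors in Ventral Thalamus, 0.06 for the midline and intralaminar profile in Ventral Thalamus and -0.15 for cytosolic ribosomal proteins in Ventral Thalamus. The blocked ribosomal call was lost without Anterior Thalamus replicate 2, Centre Median replicate 2, Medial Thalamus replicate 1, Pulvinar replicate 1 or Ventral Thalamus replicate 1 (up to 0.853). The unblocked striatum and choroid plexus calls were both lost without Medial Thalamus replicate 2, Pulvinar replicate 2, Ventral Thalamus replicate 1 or Ventral Thalamus replicate 2, and the choroid plexus call also without Anterior Thalamus replicate 1 (up to 0.133 and 0.218).

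Medial Thalamus was set apart by higher CALB2 and ADCYAP1 and lower GAD1 and ATP2B1 among single genes, none of which passed without the block. CALB2 was 2.15-fold higher at 10.05 ± 0.31 (SD, n = 2) against 8.95 (SE of the difference 0.159, adjusted p = 0.0194). ADCYAP1, the neuropeptide PACAP, was 2.05-fold higher at 8.39 ± 0.03 (SD, n = 2) against 7.35 (SE 0.128, adjusted p = 0.00712). GAD1 fell by 1.06 (SE 0.165, adjusted p = 0.0317), while its 2 other probe sets differed by -0.10 and -0.11 and the GABAergic list did not pass (camera adjusted p = 0.368 and 0.463 without and with the block). ATP2B1, a calcium pump of the plasma membrane, fell by 1.24 (SE 0.134, adjusted p = 0.00411). limma called 19 genes with the block, 8 higher and 11 lower (1236 at an unadjusted p under 0.05), and 0 without it (146 at an unadjusted p under 0.05). The 10 smallest p without the block were those of ADCYAP1, CALB2, DPYSL3, FBXW7, LOC728392, LRP8, MAG, OPN3, SYT17 and TENT5A, each at an adjusted p of 1.00, and the unblocked count was 1 without Medial Thalamus replicate 1.

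The other genes called higher in Medial Thalamus with the block were LOC728392 by 1.33 (adjusted p = 0.013), CD99, a surface glycoprotein, by 0.88, ANXA2, a membrane-binding annexin, by 0.83, DPYSL3, a cytoskeletal protein of growing axons, by 0.71, ASS1, an arginine synthesis enzyme, by 0.71, and GPX1, a glutathione peroxidase, by 0.59. Named decreases were OPN3 by -1.02 (adjusted p = 0.00411), CDS1 by -1.02, WWP1, a ubiquitin ligase, by -0.87, KIT, a receptor tyrosine kinase, by -0.84, SEPTIN4 by -0.79 and PLCB4, a phospholipase, by -0.65. Other probe sets of CDS1 and WWP1 had the opposite sign in Medial Thalamus. The actin 3' minus 5' signal of Medial Thalamus was -0.09 in replicate 1, the lowest of the 10 arrays, and 1.34 in replicate 2. With that signal as a covariate beside the block 28 genes were called, of which 8 were among the 19, so that 11 of the calls ended, and all 19 genes kept their sign. With the GAPDH signal 5 were called, all among the 19. Medial Thalamus replicate 2 had TTR, a transport protein abundant in choroid plexus, at 12.19 against 7.17 to 8.41 on the other arrays, and DCN, a connective tissue proteoglycan, at 9.51 against 8.60 to 8.97. TTR and DCN were chosen after their values were seen. The blocked count of 19 was 49 without Medial Thalamus replicate 1, 110 without Medial Thalamus replicate 2, 5 without Anterior Thalamus replicate 1, 4 without Anterior Thalamus replicate 2, 4 without Centre Median replicate 1, 12 without Pulvinar replicate 1 and 5 without Ventral Thalamus replicate 2. After quantile normalisation with the block it was 8, of which 5 were higher, and with the mean of all probe sets of a gene it was 3.

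Oligodendrocyte and myelin genes were shifted downward in Medial Thalamus, with 1 of 23 above 0 and a median of -0.34 (camera adjusted p = 7.53e-13 without the block and 2.86e-11 with it; adjusted p = 0.315 and 0.229 with an estimated correlation). Over all genes 0 members were called by limma, and adjusted over the list alone 1 was lower without the block and 14 with it. Oxidative phosphorylation genes had 6 of 55 above 0 and a median of -0.13 (5.04e-05 and 5.68e-06), the first-order relay profile had 2 of 13 above 0 and a median of -0.21 (0.000558 and 0.000922), and neurofilaments and axonal cytoskeleton genes had 5 of 21 above 0 and a median of -0.13 (0.00575 and 0.017). In these 3 lists 0 members were called over all genes, and with the block 1, 4 and 3 members were lower adjusted over the list alone. The rise of these lists in Ventral Thalamus alone lowers their differences in Medial Thalamus, as it does in the other nuclei. The midline and intralaminar profile had 13 of 16 above 0 and a median of 0.12 (0.00271 and 0.00269), with CALB2 called over all genes with the block and, adjusted over the list alone, 3 members with the block and 1 without it. Meninges and fibroblast genes had 9 of 11 above 0 and a median of 0.15 (0.00203 and 0.00502), and their median was -0.04 in replicate 1 and 0.43 in replicate 2. Microglia and macrophage genes had 15 of 18 above 0 and a median of 0.09 (0.019 and 0.0477). Of the meninges and microglia lists 0 members were called over all genes, and with the block 1 meninges gene was higher, 1 microglia gene was higher and 1 was lower adjusted over the list alone. With an estimated correlation the adjusted p = 0.902 and 0.73 for oxidative phosphorylation, 0.729 and 0.73 for the relay profile, 0.741 and 0.73 for neurofilaments, 0.787 and 0.624 for the midline profile, 0.729 and 0.708 for meninges and 0.729 and 0.708 for microglia. The actin signal of -0.09 and 1.34 and the TTR level of 12.19 in replicate 2 stood beside these lists. The myelin list passed in both fits when any 1 of the 10 arrays was left out, with adjusted p of at most 0.000451. Without Medial Thalamus replicate 2 the unblocked calls of meninges (adjusted p = 0.923), microglia (0.907), the relay profile (0.063) and neurofilaments (0.279) were lost, as were the blocked calls of meninges (0.91), the midline profile (0.0547) and oxidative phosphorylation (0.107). Without that array the meninges median was -0.04 in both fits. Without Medial Thalamus replicate 1 the unblocked midline call was lost (0.405), as was that of oxidative phosphorylation (0.714), whose median was 0.02. The blocked neurofilament call was lost without Anterior Thalamus replicate 2, Medial Thalamus replicate 2 or Ventral Thalamus replicate 2 (up to 0.487), and the blocked microglia call without any of these and without Centre Median replicate 2 or Pulvinar replicate 1 (up to 0.941). The unblocked microglia call was lost without Pulvinar replicate 1 as well.

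**Figure D5:**
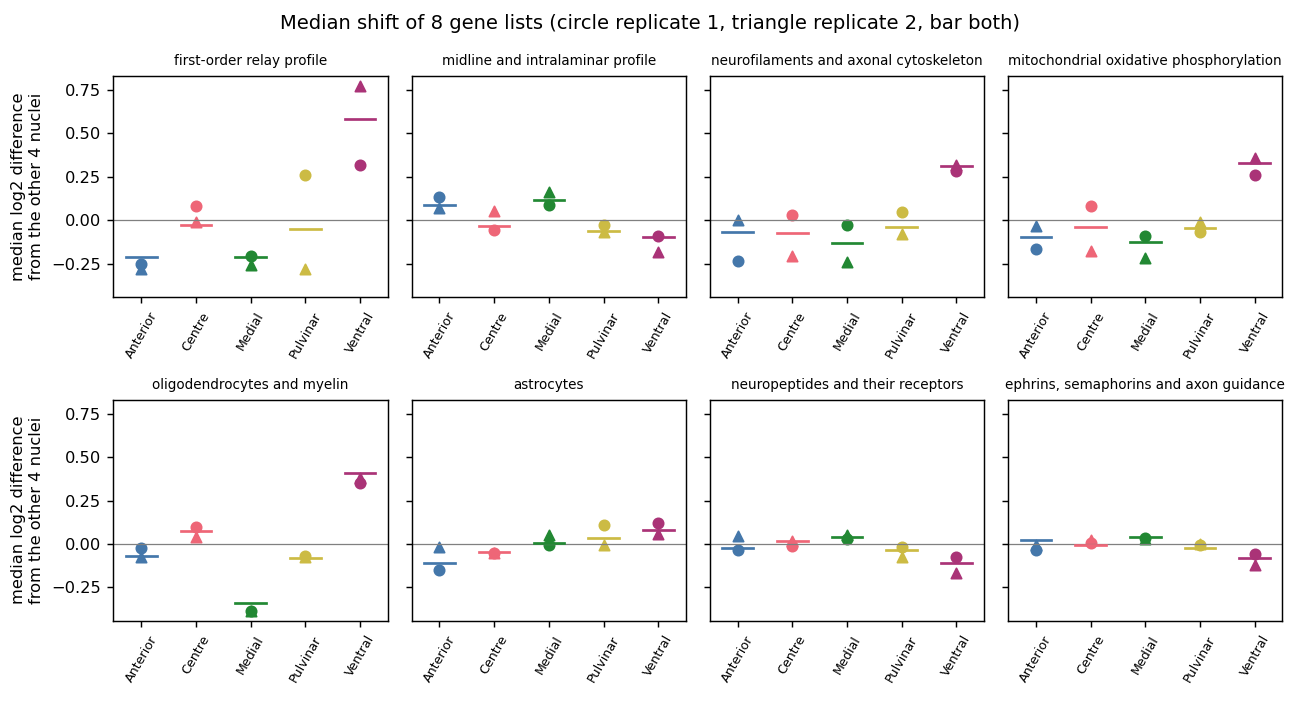
Median log2 difference of each nucleus from the mean of the other 4 is shown for 8 fixed gene lists, with circles for replicate 1, triangles for replicate 2 and bars for both. Oxidative phosphorylation, myelin, relay and neurofilament lists lie above 0 in Ventral Thalamus and below 0 in Medial Thalamus, and the astrocyte list, which passed in no nucleus, has bars between -0.11 and 0.08 and replicate values between -0.15 and 0.12.

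Pulvinar had no single gene that passed in limma, with 34 genes at an unadjusted p under 0.05 without the block and 446 with it. Of the 10 genes with the smallest p in the blocked fit, ATP2B1 stood at 11.08 ± 0.62 (SD, n = 2) against 10.25, and PSD3 at 9.16 ± 0.26 (SD, n = 2) against 8.45. Their log2 differences were 0.82 and 0.71, that of KLF13, a zinc-finger transcription factor, was 0.86, and these genes and MC4R, at -0.57, shared an adjusted p of 0.134. PDYN, the dynorphin precursor, differed by 0.69 (adjusted p = 0.192), NRXN3, a presynaptic neurexin, by 0.82 (0.352) and CHST15 by 0.66 (0.254), and BHLHE40, OPN3 and PPM1H completed the 10. Without the block, DIRAS3, EPHX1, FEM1C, KCNJ6 and LOC728392 were also among the 10, each at an adjusted p of 1.00. Genes of oligodendrocytes and myelin were shifted downward, with 7 of 23 above 0 and a median of -0.08 (camera adjusted p = 0.00323 and 0.00358, and adjusted p = 0.729 and 0.624 with an estimated correlation). The larger rise of this list in Ventral Thalamus alone lowers its difference in Pulvinar. The sex-linked list, 7 genes in all, was shifted downward (0.0322 and 0.0298; adjusted p = 0.787 and 0.708 with an estimated correlation), with 1 member above 0 and a median of -0.14, while its mean of 0.000433 had the opposite sign. XIST was low (7.22, 6.70 and 6.86, against 8.96 to 10.34) and RPS4Y1 high (8.20, 8.16 and 8.94, against 6.96 to 7.65) on the replicate 1 arrays of Anterior, Medial and Ventral Thalamus and not on those of Pulvinar. The block assumes 1 shift for all arrays of a replicate number, which would not hold if that number stood for animals of different sex. With the replicate 1 arrays split by XIST and RPS4Y1 the median was -0.15 (camera adjusted p = 0.0244). The habenula list, markers of the neighbouring epithalamus, passed without the block alone, with 3 of 11 above 0 and a median of -0.06 (0.0449 and 0.0616; adjusted p = 0.787 with an estimated correlation). No member of these 3 lists was called by limma over all genes, and adjusted over the list alone 1 habenula gene was lower with the block and 0 members of the other lists passed. With the block the count of 0 was 1 without Medial Thalamus replicate 1, 2 without Ventral Thalamus replicate 2 and 4 with the replicate 1 arrays split by XIST and RPS4Y1. The myelin call was lost in both fits without Pulvinar replicate 1, with an unblocked median of 0.05, and without the block also without Medial Thalamus replicate 2 or Ventral Thalamus replicate 2 (adjusted p of up to 0.809 and 0.351). The unblocked sex-linked and habenula calls were each lost in 6 of the 10 fits that left out 1 array (up to 0.965 and 0.801), both of them without Anterior Thalamus replicate 1, Centre Median replicate 1, Medial Thalamus replicate 2, Pulvinar replicate 2 or Ventral Thalamus replicate 1. The sex-linked call was lost also without Medial Thalamus replicate 1 and the habenula call without Pulvinar replicate 1, and the blocked sex-linked call was lost in 5 of the 10 fits (up to 0.462), those without Anterior Thalamus replicate 2, Centre Median replicate 1, Medial Thalamus replicate 2, Pulvinar replicate 2 or Ventral Thalamus replicate 1.

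Anterior Thalamus also had no single gene that passed in limma, with 36 genes at an unadjusted p under 0.05 without the block and 688 with it. TPBG had the smallest blocked adjusted p, at 0.301, and stood at 5.83 ± 0.01 (SD, n = 2) against 6.56, a log2 difference of -0.73. TAC1, the precursor of substance P, stood at 5.88 against 4.59, a difference of 1.29 (adjusted p = 0.722), and CBLN1, MC4R, NPTX2, RIMS1, CLEC2D, SERPINA7, MTTP and MYRIP completed the 10 smallest p. Without the block the 10 also included CSRP2, DIRAS3, ITGB2, SERPINI1 and SLC1A1, each at an adjusted p of 1.00. The first-order relay profile was shifted downward, with 2 of 13 above 0 and a median of -0.21 (camera adjusted p = 0.000938 without the block and 0.00171 with it). Oxidative phosphorylation genes had 9 of 55 above 0 and a median of -0.09 (0.00902 and 0.000482), and cytosolic ribosomal proteins had 5 of 43 above 0 and a median of -0.11 (0.0429 and 0.000647). The larger rise of the relay and oxidative phosphorylation lists in Ventral Thalamus alone lowers their differences in Anterior Thalamus. Microglia and macrophage genes passed without the block alone, with 4 of 18 above 0 and a median of -0.11 (0.0429 and 0.0623). With an estimated correlation the adjusted p = 0.729 and 0.73 for the relay profile, 0.965 and 0.76 for oxidative phosphorylation, 0.984 and 0.783 for ribosomal proteins and 0.74 and 0.72 for microglia. In these lists 0 members were called over all genes, and 2 relay genes were lower with the block adjusted over the list alone. Without Anterior Thalamus replicate 1 the unblocked medians turned to 0.18 for oxidative phosphorylation and 0.19 for ribosomal proteins, and both lists passed in that opposite direction (camera adjusted p = 0.00065 and 0.0397). Without Pulvinar replicate 2 the ribosomal median was 0.04. The relay call was lost without Anterior Thalamus replicate 2 in both fits and, without the block, without Anterior Thalamus replicate 1 (adjusted p of up to 0.0967 and 0.0776). The unblocked oxidative phosphorylation and ribosomal calls were lost without Centre Median replicate 2, Medial Thalamus replicate 2, Pulvinar replicate 2 or Ventral Thalamus replicate 2 (up to 0.569 and 0.761). With the block the former was lost without Anterior Thalamus replicate 1 (0.37) and the latter without Anterior Thalamus replicate 2 or Pulvinar replicate 2 (up to 0.446). The unblocked microglia call was lost without Anterior Thalamus replicate 2, Centre Median replicate 1, Medial Thalamus replicate 2, Pulvinar replicate 2 or Ventral Thalamus replicate 1 (up to 0.722). With the block the count of 0 genes was 3 without Anterior Thalamus replicate 2, 2 without Medial Thalamus replicate 1 and 1 without Ventral Thalamus replicate 1.

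In all, camera called 27 of 170 list shifts without the block and 24 with it, and 22 were called in both fits with the same direction. With an estimated correlation 0 were called in either fit, with smallest adjusted p of 0.315 and 0.229. fry, which asks whether the genes of a list move on balance in 1 direction without comparison to other genes, called 0 in either fit, with smallest adjusted p of 0.587 and 0.0548. The mixed form of fry asks whether members differ in either direction, and so shows no shift in 1 direction. It called 1 list result without the block and 39 with it, with smallest adjusted p of 4.13e-06 and 1.43e-06. The camera count without the block was 47 without Medial Thalamus replicate 1, and the count with the block was 40 without that array.

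Direct comparison of pairs of nuclei gave the most differences between Medial and Ventral Thalamus with the block, whereas without it 0 genes were called for that pair. HTR2C, a serotonin receptor, was higher in Medial Thalamus by 2.65 (means 7.48 and 4.83, SE 0.576, adjusted p = 0.0489 with the block), with 6.13 and 8.83 in the Medial Thalamus arrays of replicates 1 and 2. The latter array also had TTR at 12.19, and HTR2C is itself abundant in choroid plexus. PVALB was lower in Medial Thalamus than in Ventral Thalamus by -2.34 (means 8.60 and 10.93, SE 0.489, adjusted p = 0.0446). CBLN1 was higher in Centre Median than in Anterior Thalamus (difference of Anterior minus Centre Median -2.21), Pulvinar (2.15) and Ventral Thalamus (2.03). The other named differences were TPBG (Anterior Thalamus minus Centre Median, -1.83), CRYM and MC4R (Centre Median minus Medial Thalamus, 1.81 and 1.68), MC4R (Centre Median minus Pulvinar, 1.88) and CACNA2D3 (Centre Median minus Ventral Thalamus, 1.95). ATP2B1 and LOC728392 differed between Medial Thalamus and Pulvinar by -1.65 and 1.63, and NEFM and STK39 between Anterior and Ventral Thalamus by -2.02 and -1.02. With the block limma called 129 genes between Medial and Ventral Thalamus, 24 higher and 105 lower in Medial Thalamus. With the actin signal as a covariate, and without Medial Thalamus replicate 1, more of the called genes were higher than lower in Medial Thalamus. The excess of lower genes thus did not hold in every setting. The actin 3' minus 5' signal of these nuclei was -0.09 against 1.22 in replicate 1 and 1.34 against 1.64 in replicate 2, and the count was 23, of which 17 were higher, with that signal as a covariate and 2 with that of GAPDH. It was 45, of which 17 were higher, after quantile normalisation, 61, of which 17 were higher, with the mean of all probe sets and 224 with the split by XIST and RPS4Y1. The count of 129 was 80 without Centre Median replicate 1 or 2, 65 without Medial Thalamus replicate 1, 233 without Medial Thalamus replicate 2, 43 without Ventral Thalamus replicate 1 and 13 without Ventral Thalamus replicate 2. With the block limma called 44 between Centre Median and Ventral Thalamus, 11 between Centre Median and Pulvinar, 9 between Anterior Thalamus and Centre Median, 9 between Centre Median and Medial Thalamus, 6 between Medial Thalamus and Pulvinar and 2 between Anterior and Ventral Thalamus. The remaining 3 pairs had 0 genes, with 610 genes at an unadjusted p under 0.05 for Anterior and Medial Thalamus, 572 for Anterior Thalamus and Pulvinar and 710 for Pulvinar and Ventral Thalamus. In all 155 genes were called in at least 1 pair with the block (50 with the actin and 20 with the GAPDH covariate) and 2, MC4R and TPBG, without it. Without the block MC4R was called in Centre Median against each of the other 4 nuclei and TPBG against Anterior Thalamus. The unblocked count fell to 0 without Anterior Thalamus replicate 1 or 2, Centre Median replicate 1 or 2, Medial Thalamus replicate 2, Pulvinar replicate 1 or 2 and Ventral Thalamus replicate 1 or 2, and to 1 without Medial Thalamus replicate 1. The blocked count of 155 was 84 without Centre Median replicate 1, 100 without Centre Median replicate 2, 306 without Medial Thalamus replicate 2, 78 without Ventral Thalamus replicate 1 and 39 without Ventral Thalamus replicate 2.

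Genes unique to a nucleus by the stricter definition were MC4R, TPBG and DIRAS3 in Centre Median without the block, and 48 genes with it, 38 higher and 10 lower. The 48 were judged after the replicate shift was subtracted, and on the values as they are not all lay beyond every other array. CBLN1, for example, was at 8.67 in Centre Median replicate 2 and at 8.86 in Medial Thalamus replicate 1. Centre Median had 13 of the 48, 11 higher and 2 lower, including CBLN1, CRYM, SERPINI1 and LMO1, with PCP4 and NPTX2 lower. Medial Thalamus had 10, 6 higher and 4 lower, including ADCYAP1, CALB2 and ANXA2, with GAD1 and KIT lower. Ventral Thalamus had 25, 21 higher and 4 lower, including NEFH, NEFM, NEFL, MAG and CNP, with CALB2, PLXNC1, SCN2A and B3GALNT1 lower. Anterior Thalamus and Pulvinar had 0. The actin 3' minus 5' signal of 1.22 and 1.64 stood beside the Ventral Thalamus genes. The unblocked count was 0 without Centre Median replicate 1 or 2, and 1 without Anterior Thalamus replicate 1 or 2, Pulvinar replicate 1 or 2 or Ventral Thalamus replicate 2. The blocked count was 28 without Anterior Thalamus replicate 1, 23 without Centre Median replicate 1, 78 without Medial Thalamus replicate 1, 113 without Medial Thalamus replicate 2 and 18 without Ventral Thalamus replicate 2.

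Whether the arrays of a nucleus resembled each other more than other pairs was tested with the 1000 most variable genes. The mean distance between the 2 arrays of a nucleus was 33.3, against a mean of 25.2 over all 945 ways to pair the arrays (one-sided exact permutation p = 0.875, with a smallest possible p of 0.00106). Arrays that shared a replicate number lay 14.3 apart on average. Among the 120 pairings that join a replicate 1 with a replicate 2 array, the exact permutation p was 0.0167 for the values as they are and 0.00833, the smallest that these pairings can give, after the mean of each replicate set was removed. With the means removed, arrays of the same nucleus lay 10.2 apart against 13.4 over all 945 pairings (exact permutation p = 0.00106). Removal of the means pushes arrays of the same replicate number apart, so the latter p does not rest on nuclei alone.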

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

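The settings that join the replicate block with another choice, the actin and GAPDH covariates, the split by XIST and RPS4Y1, the pairings across replicate numbers and quantile normalisation of the list tests were chosen after the data were seen, and the other settings before. Over the settings run, the named genes kept their sign and their side of the threshold in 1128 values without the block and 1622 with it. Genes that were not called and stayed so are counted among these. Without the block only 3 of the named genes were called, so most of the 1128 values are of genes not called. The 22 calls lost without the block, given next, all belong to those 3 genes. The call was lost in 22 and 452 values and gained in 23 and 4, and no named gene changed sign in these settings, whereas 8 of 40 comparisons with single other probe sets of the named genes had the opposite sign. A nucleus with 1 array left was assumed to vary like the others. The cause of a change was not tested except where fewer genes or arrays entered the fit or the threshold itself was changed. For arrays, signal over background limits what a low intensity shows, and the replicate 1 and replicate 2 arrays differ in their lowest intensities.

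Without the block the F test gave 1 gene after median centring, with the 25th percentile filter, with the mean of probe sets, with array weights and at an adjusted p under 0.1, against 0. The filter at the median of gene means left 0 genes in Centre Median, 0 nucleus-specific genes and 0 genes in pairs. Genes in pairs numbered 1 with all probe sets tested separately and 1 with the probe set of highest variance. List calls numbered 0 with an estimated correlation, 0 with fry in 1 direction and 1 with its mixed form. The replicate block gave 47 genes in the F test, 21 in Centre Median, 19 in Medial Thalamus, 63 in Ventral Thalamus, 48 nucleus-specific and 155 in pairs. The exact permutation p of replicate similarity was 0.00106 with replicate means removed, 0.0167 over cross-replicate pairings and 0.00833 with both, the smallest possible value of that test.

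With the block, quantile normalisation gave 22 genes in the F test, 8 in Medial Thalamus (5 higher), 28 in Ventral Thalamus (18 higher), 29 nucleus-specific and 71 in pairs. The median filter gave 10 in Centre Median and 38 in Medial Thalamus, and the 25th percentile filter 45 in Medial Thalamus and 233 in pairs, with fewer genes tested. The mean of probe sets gave 14 in the F test, 3 in Medial Thalamus, 17 in Ventral Thalamus, 18 nucleus-specific and 80 in pairs. Leaving out the variance trend gave 24 in the F test and 13 in Centre Median. Array weights gave 37 in Centre Median, 5 in Medial Thalamus and 159 in Ventral Thalamus. An adjusted p under 0.1 gave 89 in the F test, 36 in Centre Median, 71 in Medial Thalamus, 144 in Ventral Thalamus and 425 in pairs. A pseudocount of 16 gave 11 in Medial Thalamus.

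With the block and the actin covariate, counts were 26 in the F test, 38 in Centre Median, 28 in Medial Thalamus, 8 in Ventral Thalamus (4 higher) and 50 in pairs. With the GAPDH covariate they were 9 in the F test, 13 in Centre Median, 5 in Medial Thalamus, 1 in Ventral Thalamus, 16 nucleus-specific and 20 in pairs. The split by XIST and RPS4Y1 gave 76 in the F test, 12 in Centre Median, 4 in Pulvinar, 95 in Ventral Thalamus, 254 in pairs and 37 list calls. A 2-fold minimum left 10 nucleus-specific genes and no minimum left 94. With an estimated correlation 0 lists were called, 0 with fry in 1 direction and 39 with its mixed form.

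Leaving out each array in turn gave, without the block, 0 to 3 genes in Centre Median, 0 to 1 in Medial Thalamus, 0 to 4 nucleus-specific, 0 to 1 in pairs and 21 to 47 list calls. With the block it gave 13 to 95 in the F test, 0 to 3 in Anterior Thalamus, 4 to 42 in Centre Median, 4 to 110 in Medial Thalamus, 0 to 2 in Pulvinar, 0 to 106 in Ventral Thalamus, 18 to 113 nucleus-specific, 39 to 306 in pairs and 18 to 40 list calls. Ventral Thalamus had 0 without Ventral Thalamus replicate 2, and Medial Thalamus 110 without Medial Thalamus replicate 2. Cytosolic ribosomal proteins in Ventral Thalamus had a median of -0.019 after quantile normalisation in both fits and -0.092 with the block and actin covariate.

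Without 1 array, medians without the block ranged from -0.44 to 0.19 for cytosolic ribosomal proteins in Anterior Thalamus, from -0.15 to 0.37 in Centre Median and from -0.15 to 0.33 in Ventral Thalamus, where they ranged from -0.031 to 0.22 with the block. Oxidative phosphorylation ranged from -0.41 to 0.18 in Anterior Thalamus and from -0.33 to 0.025 in Medial Thalamus. Oligodendrocytes and myelin in Pulvinar ranged from -0.15 to 0.055. Meninges and fibroblasts in Medial Thalamus ranged from -0.045 to 0.35 without the block and from -0.042 to 0.43 with it. Of the list results, 303 without the block and 395 with it kept their direction and their side of the threshold, 134 and 98 lost their call, 15 and 24 gained one, and 11 and 4 reversed. Direction here is that of camera, and a result was counted as reversed only if the sign of its median changed too. Medians that turned while the camera direction held were not counted, as for neuropeptides in Ventral Thalamus without replicate 2.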

Other observations

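Of the tests in this part, those of other matchings of the arrays, of 3' bias among single genes and of the opposition of Medial and Ventral Thalamus were chosen before their results were seen. Those of quantile normalisation, of cell type shares, of 3' bias in gene lists, of neighbouring-tissue markers and of Y-linked genes were chosen after, and the bounds of the list and neighbouring-tissue tests were set with their values in view.

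Several genes known from the habenula, a neighbour of the medial thalamus, stood out on Medial Thalamus replicate 2 alone. POU4F1, a transcription factor of habenular neurons, was at 7.36 there and at 5.56 in Medial Thalamus replicate 1, and NR4A2, a nuclear receptor, was at 7.76 against 5.25 to 5.87 on the other arrays. The genes named in this part were chosen after their values were seen. XIST, the transcript of the inactive X chromosome, was at 7.22, 6.70 and 6.86 on the replicate 1 arrays of Anterior, Medial and Ventral Thalamus and between 8.96 and 10.34 on the other 7 arrays, while RPS4Y1, a Y-linked ribosomal gene, was at 8.20, 8.16 and 8.94 against 6.96 to 7.65. Of 5 other measured Y-linked genes 0 were higher in each of these 3 arrays than in all others, and 2 had their highest value in 1 of the 3. These 5 genes cannot decide the sex of the animals, since they varied little among the replicate 1 arrays. DDX3Y lay at 4.97 to 5.16 there, KDM5D at 7.10 to 7.34 and EIF1AY at 5.29 to 5.53. USP9Y lay at 4.50 to 4.67 and UTY at 7.42 to 7.69. XIST and RPS4Y1 shifted in opposite directions on the same 3 arrays, which points to animals of different sex in replicate 1. Both genes belong to the sex-linked list fixed beforehand but were singled out from it after their values were seen, so this stayed unproven. Of the other arrays, Centre Median replicate 1 lay nearest to these 3, with XIST at 8.96 and RPS4Y1 at 7.65. If replicate 1 held such animals, the block would not remove the differences between them.

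Whether chance matching of arrays gives as many genes was tested with 100 of the 120 ways to match replicate 1 with replicate 2 arrays, the real one included. The real matching gave 47 genes in the blocked F test, and 1 of the 100, the real one, gave that many. This argues against chance matching at this count but does not exclude it, since the rest of the 120 were not run. The highest of the others gave 43 and kept 3 of the real pairs, while the matchings that kept 0 real pairs gave at most 1 gene.

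The first pattern weighed was the Ventral Thalamus difference, in 63 genes and 4 lists, beside a higher actin 3' minus 5' signal. Array-wide intensity distributions were already close after RMA, with log2 medians of 6.57 to 6.67 on the 10 arrays, so quantile normalisation could change little. The median ratio between differences after and before it was 0.942 (quartiles 0.893 to 0.972), although only 27 of the 63 genes still passed. The ratio shows only that the distributions left after RMA hold little of these differences. The myelin list rose (median 0.411, lower quartile 0.201), which argues against fewer oligodendrocytes, although 3' bias may hold part of that rise. A larger share of neurons with fewer astrocytes stays open, since myelin genes do not bear on astrocytes. The astrocyte list had a median of 0.080 (quartiles -0.107 to 0.220) and the pan-neuronal list one of 0.109 (quartiles -0.035 to 0.373). With the block and the actin covariate the myelin list kept a mean difference of 0.346 over arrays (SE 0.0874, lower 95% bound 0.0684, not adjusted for 4 lists). This argues only weakly against 3' bias as the whole cause, since 4 lists were tried and 3 residual degrees of freedom remained. Slopes in the other 8 arrays predicted 0.704 of the median of the myelin list, so a large part stays open. These slopes were fitted with the block and without a term for the nucleus. Medial Thalamus replicate 1 weighs most in them, with an actin signal of -0.09. Anterior Thalamus, Centre Median and Pulvinar lay at 0.34 to 0.46 in replicate 1. The predicted shares therefore cannot separate 3' bias from a difference of Medial Thalamus. With the actin covariate the medians went from 0.33 to 0.37 for oxidative phosphorylation, 0.58 to 0.78 for the relay list and 0.31 to 0.35 for neurofilaments. At its preset correlation camera still called these lists (adjusted p = 3.15e-10, 5.14e-08 and 2.52e-05). With an estimated correlation, tried without the covariate, it called none of them. The predicted shares of these lists were 0.165, 0.527 and -0.0227. For these lists (means 0.331, 0.857 and 0.497, SE 0.148, 0.442 and 0.175) and the 63 genes (predicted share 0.488, quartiles 0.146 to 0.746), 3' bias and a difference between nuclei still cannot be told apart, since the lists' 95% intervals over arrays include 0 with 3 residual degrees of freedom and the shares of the genes lie on both sides of 0.5.

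The second pattern was the raised markers of neighbouring tissue on Medial Thalamus replicate 2. Among the replicate 2 arrays that array was highest for 9 of 11 habenula genes, 9 of 11 meninges genes and 6 of 13 choroid plexus and ependyma genes, against 19.7% of all genes, and no p is given because these values drew attention to the pattern and the genes share 1 array. Of the 4 most abundant members of each list there, 2 for choroid plexus or ependyma in that punch, 2 for habenula and 2 for meninges lay above every other array, among them TTR at 12.19 (7.17 to 8.41 elsewhere), NR4A2 at 7.76 (5.25 to 5.87) and DCN at 9.51 (8.60 to 8.97). The others did not, namely FOLR1 at 10.35 (9.06 to 10.48), TMEM47 at 10.30 (9.23 to 10.38), ETV1 at 8.65 (7.60 to 10.06), CHRNA3 at 8.31 (7.48 to 8.43), FN1 at 8.99 (8.55 to 9.75) and COL1A1 at 8.31 (8.06 to 8.38). Whether this punch held any of these tissues or the medial nucleus differed within itself cannot be told apart, since thalamic tissue may express these genes and each tissue had members on both sides.

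The third pattern was that genes higher in Medial Thalamus tended to be lower in Ventral Thalamus. Deviations from the other 3 nuclei, taken from opposite replicate numbers so that no array was shared, correlated across genes at -0.163 and -0.181, and their mean of -0.172 was the lowest of the 10 pairs of nuclei, with -0.0416 the next lowest. Genes are not independent replicates, so no p is given. The second principal component of the same arrays placed these nuclei at its ends in each replicate set. Ventral Thalamus lay at -10.7 and -14.0 and Medial Thalamus at 5.04 and 11.9. A low r for this pair was therefore likely beforehand. It describes a shared axis with these nuclei at its ends in these arrays and is no separate support for one. RNA quality along the same axis stays open, since the actin signal was lowest in Medial Thalamus (-0.09) and highest in Ventral Thalamus (1.22) in replicate 1, although in replicate 2 Medial Thalamus (1.34) was not the lowest.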
